A study of Rattus norvegicus with 8 samples.

How the data were processed

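RNA of rat thoracic aorta was sequenced in 8 libraries, 4 from vehicle controls and 4 from nitroglycerin-treated rats, after rRNA depletion with the Ribo-Zero Gold kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2, with the genome builds Rnor_6.0 and mm8, without saying which tool or build served which step. The deposited gene table gives FPKM per gene and library for 27742 rows, of which 19625 include an annotated transcript and 8117 hold only assembled transcripts. The deposited lncRNA table gives FPKM and coverage per base for 4686 assembled transcripts, with 2 coding-potential scores (CPC and CNCI), per the file headers. The CPC score reached at most -1 and the CNCI score was below 0 throughout. Coordinates are those of the lncRNA table. Of these transcripts, 86.2% had a single exon.

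FPKM values are relative, so a transcript that takes more of a library lowers all others, and they are not counts. The ratio of coverage to FPKM was constant within each library and was taken as the aligned sequence in gigabases. Counts of reads per gene were not analysed here, so count-based intervals were not computed. An exact 0 can be a failed estimate, since Mt-co1, abundant in most tissues, was near 0 in some libraries, and per-library values are given for loci listed at 0.

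Gene values were tested as log2(FPKM + 1) for the 12977 rows with at least 1 FPKM in at least 4 libraries, and lncRNA values as log2(FPKM + 0.1) for the 2390 transcripts with at least 0.1 FPKM in at least 4. Fold changes are on these scales and understate those of low genes. Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. A size rule added an absolute log2 difference of at least 1. Gene lists (37, with 795 entries) were written before the data were examined, and the 27 with at least 5 measured members were tested with camera at a preset correlation of 0.01. The fat-marker score is the mean log2 value of brown and general adipocyte markers. Single values were compared by two-sided exact permutation tests over 70 splits, whose smallest p is 0.0286. Python 3.11.15 and matplotlib 3.10.9 drew the plots.

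Because the median gene differed between groups, libraries were also rescaled by median-of-ratios factors over tested rows above 0 in every library. The factors were 0.742 to 0.996 in controls and 1.07 to 1.22 in nitroglycerin libraries. Rescaling was an alternative planned before the data were examined. Showing its calls beside the main ones was decided afterwards, and factors from 2 other sets of genes were tried, 1 of them during a first look at the data.

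Named genes followed a rule fixed beforehand: 15 genes of nitrate action and tolerance where measured, the 10 lowest adjusted p in each direction among rows with a symbol and at least 1 FPKM in a group (or those that passed and up to 5 more in all, as values), up to 4 members of each called list, and the 5 lncRNAs of lowest p in each direction. Prkg1 had no row under that symbol. Other list members given as examples were chosen after their values were seen. Rows with near-identical sequence, such as the 2 rows that the file describes as collagen type I alpha 2, were left unnamed because reads can be split between them.

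The steps were tested on simulated data with known changes. Of genes changed by a log2 difference of 0.585, 1 and 2, 10.4%, 47.8% and 90.9% were recovered among 12977, and 3 of 102 calls were false. For lncRNAs, 1.49%, 19.4% and 51.5% were recovered at log2 differences of 1, 2 and 4 among 2390 transcripts. Values were simulated independently, with changes in both directions and no difference between libraries in these fits. The rates therefore need not hold for the measured libraries, where most genes were higher in 1 group. Alternatives covered the pseudocount, filters, scaling, test options, the replicate number as a block, the fat-marker score as a covariate, 1 row per symbol, and each library left out in turn.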

Results

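Thoracic aorta of male Sprague Dawley rats was profiled by sequencing of ribosomal-RNA-depleted total RNA. The labels give an age of 12 weeks and a body weight of 180 to 200 g, which is low for males of that age, so the age or the weight is uncertain. Their extraction protocol speaks of an adipose type, although the tissue is given as aorta. One group of 4 libraries came from rats given nitroglycerin (glyceryl trinitrate, GTN), an organic nitrate vasodilator, at 100 mg/kg under the skin 3 times a day for 3 days. The control group of 4 libraries came from rats given the ethanol vehicle. The comparison asks which genes and long non-coding RNAs (lncRNAs) differ in the aorta after a dosing schedule meant to produce nitrate tolerance. The labels do not say whether each library came from its own rat, so the p-values measure the spread between these samples. Aligned sequence was 7.48 to 8.86 Gb per control library and 6.77 to 8.39 Gb per nitroglycerin library (two-sided exact permutation p = 0.343, n = 4 per group).

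Nitroglycerin aortas had higher values of the clock gene Per3, at 4.98 ± 0.521 FPKM against 1.32 ± 0.125 in controls (mean ± SD, n = 4 per group). Xbp1, a transcription factor of the unfolded protein response, rose from 4.11 ± 0.835 to 11.4 ± 0.679 FPKM. Sparc, a secreted matrix protein, fell from 1380 ± 199.7 to 636 ± 89.2 FPKM. Col4a1, a basement membrane collagen chain, fell from 88.2 ± 12.6 to 47.3 ± 2.5 FPKM. By limma with Benjamini-Hochberg adjustment on log2(FPKM + 1), 167 of 12977 genes rose and 8 fell at an adjusted p under 0.05, and 40 and 5 of these also had a log2 difference of at least 1.

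Most genes were higher in the nitroglycerin libraries: the median log2 difference of all 12977 genes was 0.30, and 86.6% were above 0. The 100 rows of highest mean held 59.6 ± 8.78% of the summed FPKM in controls and 48.5 ± 1.39% in nitroglycerin libraries (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). Changes were therefore also measured after median-of-ratios rescaling, which brought the median to 0.01. After rescaling, 4 genes rose and 13 fell by the same limma test. The genes called under both scalings numbered 10, of which 4 were higher and 6 lower. All 167 genes that rose as deposited kept a log2 difference above 0, and 158 of them kept an unadjusted p under 0.05. All 167 were already above the median shift and were picked from the same libraries, so this outcome was largely fixed by their choice.

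Per3 had a log2 difference of 1.37 (SE 0.11, limma adjusted p = 0.00349 after Benjamini-Hochberg), which was 1.07 above the median gene, and 1.09 after rescaling (adjusted p = 0.0226). Nr1d2, a nuclear receptor of the clock, rose from 1.38 ± 0.434 to 4.21 ± 0.548 FPKM, a log2 difference of 1.14 (SE 0.15, limma adjusted p = 0.0413). After rescaling its difference was 0.86 (SE 0.18), which did not pass over all genes (limma adjusted p = 0.124). Xbp1 had a log2 difference of 1.29 (limma adjusted p = 0.0148), and 0.96 after rescaling (adjusted p = 0.0327). The uncharacterised gene AC104053.1 rose from 1.47 ± 0.162 to 4.66 ± 0.499 FPKM under both scalings. The other 6 of the 10 with the lowest adjusted p were Chi3l1 (a secreted chitinase-like protein), Adamts8 (a metalloprotease), Mthfd1 (an enzyme of folate metabolism), Abcb6 (a porphyrin transporter), Angptl2 (a secreted angiopoietin-like protein) and Tars2 (the mitochondrial threonyl-tRNA synthetase). Chi3l1 rose from 1.33 ± 0.402 to 4.70 ± 0.687 FPKM and Angptl2 from 9.31 ± 0.627 to 17.1 ± 1.09 FPKM. None of those 6 passed after rescaling, where Chi3l1 kept a log2 difference of 1.02 (SE 0.15, limma adjusted p = 0.0536) and Angptl2 one of 0.45 (SE 0.11, adjusted p = 0.166).

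Among the 8 genes that fell, Col4a1 had a log2 difference of -0.88 (SE 0.14, limma adjusted p = 0.0442 after Benjamini-Hochberg), and -1.26 after rescaling (adjusted p = 0.023). Sparc had a log2 difference of -1.12 (limma adjusted p = 0.0442), and -1.50 after rescaling (adjusted p = 0.0711). Adamts17, a metalloprotease, fell from 1.90 ± 0.211 to 0.647 ± 0.0478 FPKM, and Ckm, the muscle creatine kinase, from 9.78 ± 0.825 to 5.06 ± 1.35 FPKM, both under both scalings. AC115473.1 fell from 184 ± 17.2 to 79.3 ± 26.4 FPKM, a log2 difference of -1.26 (limma adjusted p = 0.0492), and -1.64 after rescaling (adjusted p = 0.0667). The other 3 were assembled loci with no annotated transcript that carry the symbols Cdc37, Hcfc2 and Lsr. The Cdc37 locus (MSTRG.19477) read 2.43, 3.06, 2.53 and 3.42 FPKM in the controls and was listed at 0 in all 4 nitroglycerin libraries, while the annotated Cdc37 row read 7.61 ± 1.06 and 9.61 ± 0.253 FPKM. Col5a1, next by p, stood at 39.5 ± 5.83 and 25.1 ± 1.75 FPKM (limma adjusted p = 0.0581) and passed after rescaling (adjusted p = 0.0226).

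**Figure D1:**
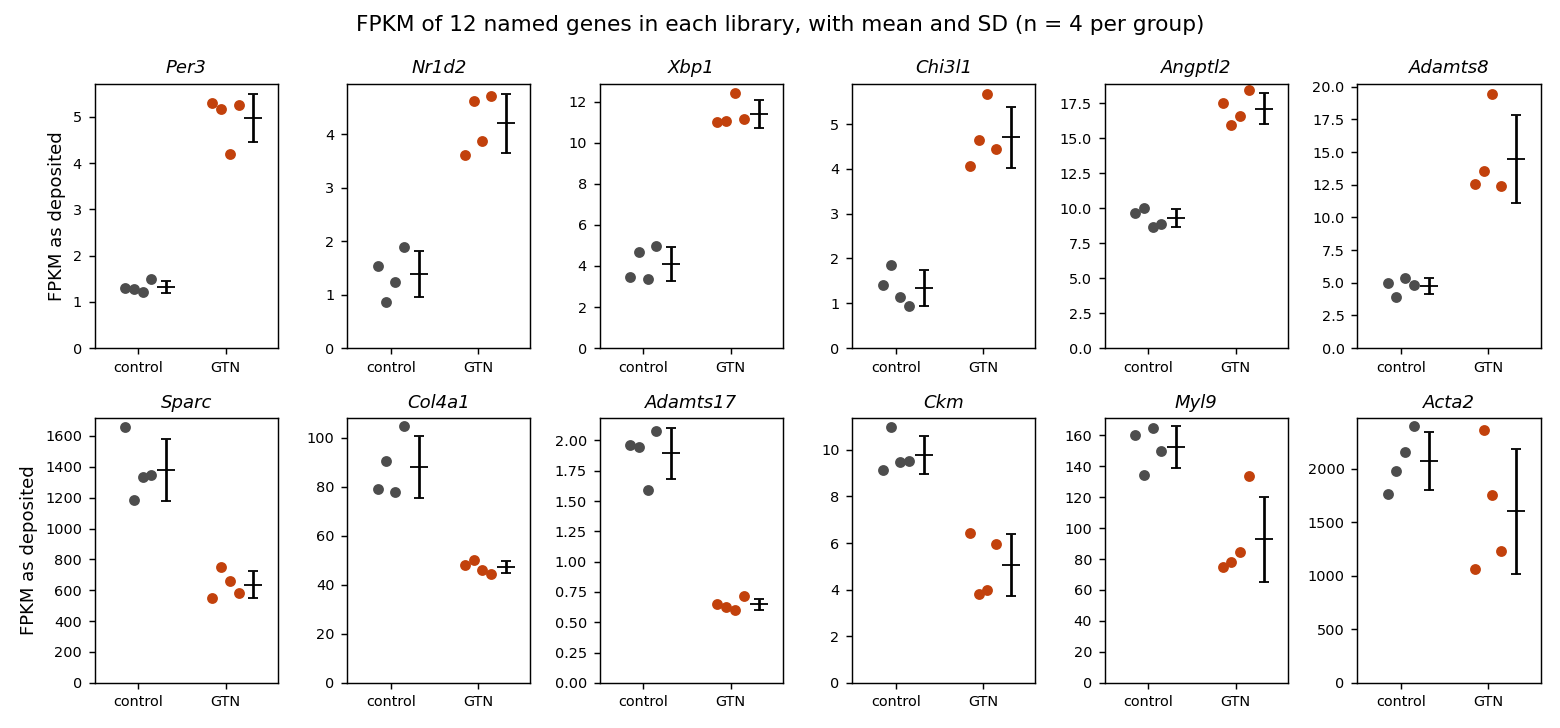
FPKM as deposited (vertical axes, from 0) of 12 named genes in each control and nitroglycerin (GTN) library; points are libraries, bars the mean ± SD of 4 libraries. Per3 lies at 4.98 ± 0.521 against 1.32 ± 0.125 FPKM and Col4a1 at 47.3 ± 2.5 against 88.2 ± 12.6 FPKM, while the groups of Acta2 overlap.

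The number of genes called changed with each library left out. It was 284 without nitroglycerin replicate 2, and from 5 to 65 without any other library. The lowest, 5, came without control replicate 4 or nitroglycerin replicate 4. At an unadjusted p under 0.05, limma gave 3348 to 5132 genes with a library left out. Without nitroglycerin replicate 1, whose fat-marker score of 3.51 exceeded the other nitroglycerin libraries, 10 were called. With that score as a covariate, 3 genes were called, and with a pseudocount of 0.1 there were 7. At an unadjusted p under 0.05 limma gave 3703 and 4513 genes in these fits, against 4564 in the main test. Of those 4564, 4431 were higher, so the count largely follows the shift of most genes. After rescaling it was 1550, of which 714 were higher and 836 lower. Over all alternatives the log2 difference of Per3 stayed between 1.08 and 1.84 and that of Xbp1 between 0.96 and 1.47.

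Of 30 measured genes of extracellular matrix and remodelling, 2 fell in nitroglycerin aortas (Sparc and Col4a1) and none rose over all genes tested. Adjusted over the list alone, 5 were lower and 2 higher, and 11 and 2 after rescaling. Examples were the fibrillar collagen gene Col1a1 at 1779 ± 302 and 1151 ± 33.5 FPKM and Col15a1 at 52.1 ± 6.05 and 32.1 ± 8.78 FPKM. The higher members were the metalloprotease Mmp2, at 137 ± 35.6 and 266 ± 51.2 FPKM, and the protease inhibitor Timp3, at 43.6 ± 9.01 and 116 ± 39.9 FPKM.

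The matrix list passed camera (limma) as lower than other genes at a preset correlation, with a Benjamini-Hochberg adjusted p of 1.25e-08 as deposited and 2.02e-05 after rescaling. That call was lost with an estimated correlation (camera adjusted p = 0.278 as deposited and 0.269 after rescaling). As deposited its median log2 difference was -0.003 and its mean 0.02, so the test describes a lag behind other genes, and after rescaling the median was -0.37. Of 16 smooth muscle contractile markers, none passed over all genes. Adjusted over the list alone, 1 was higher and 1 lower as deposited, and 0 and 4 after rescaling. The higher member was the leiomodin gene Lmod1, at 10.4 ± 1.12 and 19.1 ± 4.75 FPKM. The light chain gene Myl9 stood at 152 ± 13.6 and 92.7 ± 27.6 FPKM, the integrin gene Itga8 at 211 ± 28.9 and 148 ± 22.9, the calponin gene Cnn1 at 88.8 ± 15.7 and 56.3 ± 26.0, and smooth muscle actin Acta2 at 2075 ± 270.3 and 1602 ± 585 FPKM. That list passed camera as lower (limma, adjusted p = 3.98e-05 as deposited and 0.000436 after rescaling), but not with an estimated correlation (adjusted p = 0.278 and 0.398). Its median as deposited was 0.02, its mean -0.05.

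Of 6 measured skeletal muscle markers only Ckm fell. The list passed camera as lower (limma, adjusted p = 0.00186, and 0.0131 after rescaling) but not with an estimated correlation (adjusted p = 0.241 and 0.269). Its estimated correlations, -0.099 and -0.012, lay below the preset 0.01, so stronger correlation among its members does not account for that loss. Acta1, the skeletal actin gene, stood at 13.0 ± 4.77 and 7.53 ± 4.39 FPKM, Casq1 at 1.16 ± 0.290 and 1.05 ± 0.258, and Eno3 at 4.17 ± 0.910 and 4.14 ± 0.83 FPKM. The means of the other members were higher with nitroglycerin, with Mybpc2 at 1.02 ± 0.240 and 1.63 ± 0.381 and Tnnt3 at 4.07 ± 1.44 and 4.68 ± 1.15 FPKM. Of the 35 splits of the 8 libraries into groups of 4, 26 gave at least the 3 lists called as deposited and 12 at least the 7 called after rescaling.

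After rescaling, camera at the preset correlation also called 3 lists as higher and 1 more as lower. With an estimated correlation none of these 4 was called, at a camera adjusted p of 0.269 for the inflammatory list and 0.596 for each of the other 3. Of 7 measured inflammatory and adhesion genes, the leukocyte adhesion genes Vcam1 (3.47 ± 0.860 to 12.8 ± 4.70 FPKM) and Icam1 (1.83 ± 0.241 to 3.93 ± 0.671 FPKM) rose over all genes as deposited, and both were higher adjusted over the list alone after rescaling. Markers of other cell types moved with them as deposited. Of 16 endothelial markers, Esam (3.90 ± 0.281 to 8.23 ± 1.51 FPKM) and Eng (11.1 ± 0.693 to 17.2 ± 1.37 FPKM) rose over all genes, and of 15 macrophage markers Cd163 rose (1.91 ± 0.194 to 4.92 ± 1.48 FPKM). After rescaling none of these 3 passed over all genes, and camera called neither list (limma adjusted p = 0.0636 and 0.343). Among 14 genes of nitrate bioactivation, the aldehyde dehydrogenase gene Aldh3a1 (6.73 ± 0.946 to 13.4 ± 1.70 FPKM) and the glutathione transferase gene Gsta1 (3.74 ± 0.505 to 8.14 ± 1.98 FPKM) rose as deposited. Adjusted over that list alone after rescaling, 4 were higher and 1 lower. Among 20 genes of oxidant production and antioxidant defence, the metallothionein gene Mt2A rose as deposited. Its nitroglycerin libraries read 10.8, 11.7, 44.6 and 9.21 FPKM against 2.36 ± 0.816 in controls, a log2 difference of 2.31, and 1.81 without nitroglycerin replicate 3. These example genes were chosen after their values were seen. Rescaled camera adjusted p-values (limma) were 0.0025, 0.0131 and 0.0131 for these lists, and 0.0311 for the list of smooth muscle calcium and RhoA signalling, called as lower. Of its 25 measured genes, 0 passed limma over all genes or adjusted over the list alone after rescaling, and 4 were lower and 0 higher at an unadjusted p under 0.05. As deposited these counts were 0 lower and 6 higher. Its median log2 difference was 0.17 as deposited and -0.16 after rescaling. The remaining 20 lists were not called after rescaling (camera adjusted p from 0.0605 to 0.979), nor were the 11 general and 7 brown adipocyte markers as deposited (limma camera adjusted p = 0.960 and 0.878).

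**Figure D2:**
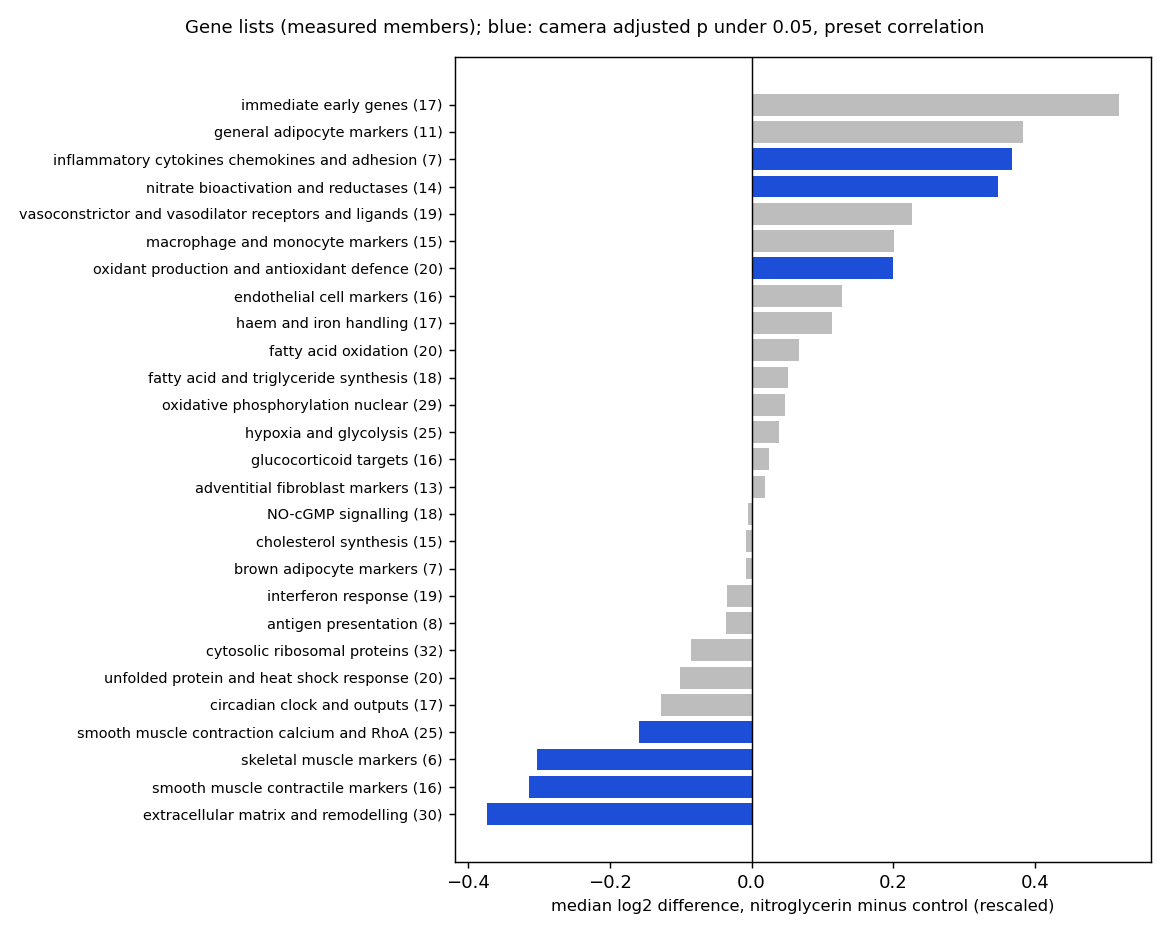
Median log2 difference (horizontal axis, nitroglycerin minus control, rescaled libraries) of 27 gene lists, with the measured members in brackets; blue marks the 7 lists with a camera adjusted p under 0.05 at the preset correlation, none of which was called with an estimated one. The matrix list lies lowest at -0.37. The uncalled lists of immediate early genes (0.52) and general adipocyte markers (0.38) lie highest, above the inflammatory list at 0.37, the highest of the called lists.

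The genes of nitrate action and tolerance named beforehand did not pass the test under either scaling, where measured. Aldh2, the mitochondrial enzyme that bioactivates nitroglycerin, stood at 101 ± 10.9 FPKM in controls and 116 ± 10.2 in nitroglycerin aortas (limma adjusted p = 0.324). The soluble guanylate cyclase subunit genes Gucy1a3 and Gucy1b3 stood at 9.12 ± 1.70 and 11.0 ± 2.39, and at 7.24 ± 0.980 and 9.82 ± 2.89 FPKM. Pde5a, a cyclic GMP phosphodiesterase, had the lowest adjusted p of these, at 5.57 ± 0.825 and 8.15 ± 0.527 FPKM (limma adjusted p = 0.0615, and 0.685 after rescaling). The angiotensin receptor gene Agtr1a stood at 3.73 ± 1.32 and 5.94 ± 0.691 FPKM, and endothelin Edn1 at 0.826 ± 0.301 and 1.51 ± 0.238 FPKM. Pde1a, Pde3a, Nos3, Ednra, Cybb and Hmox1 did not pass either, with limma adjusted p-values from 0.0992 to 0.300 as deposited. Pde1c and Nox1 were under the filter. None of the 18 measured NO-cGMP genes passed over all genes, 2 were higher adjusted over the list alone as deposited (Npr1, a natriuretic peptide receptor gene named after its value was seen, and Pde5a) and 0 after rescaling, and camera did not call the list (limma, adjusted p = 0.878).

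Of 2390 lncRNA transcripts tested, 1 changed. MSTRG.19477.1, a single-exon transcript within an intron of Cdc37 (chromosome 8, 22156640 to 22160206, minus strand), is the same locus as the Cdc37 row above. It was listed at 0 in all nitroglycerin libraries (limma adjusted p = 0.0234 after Benjamini-Hochberg, and 0.00943 after rescaling). At an unadjusted p under 0.05 there were 182 higher and 27 lower transcripts as deposited, and 67 and 51 after rescaling. Among lower transcripts, the next lowest p-values belonged to MSTRG.10740.1, MSTRG.2333.1 (within an intron of Fas), MSTRG.5462.1 and MSTRG.14198.1, each above 0 in every control library and listed at 0 in every nitroglycerin library. MSTRG.18153.1 (within an intron of Pym1) and MSTRG.6484.1 (within an intron of Ppat) had the opposite layout and the lowest p-values among higher transcripts. MSTRG.16834.1, MSTRG.15963.1 and MSTRG.2218.1 (antisense to Smarca2) came next among these, the last at 0.572 ± 0.132 and 2.37 ± 0.794 FPKM. None of these others passed, with a limma adjusted p from 0.0964 to 0.206. The MSTRG.19477.1 call was lost without any 1 control library and without nitroglycerin replicate 1. It was also lost with the fat-marker covariate, with the replicate number as a block and with robust eBayes (limma adjusted p of up to 0.296 over these settings). At least 1 transcript was called in 10 of the 35 splits of the libraries.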

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

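Of 147 groups of 4 libraries examined, 10 had 1 library far from the other 3 (6.80%), where chance gives about 1 in 20. All are given as values, and no explanation was tested for them. Control replicate 4 had an Edn1 value of 1.28 FPKM against 0.670 to 0.679 in the other controls. Control replicate 3 had 1.23 FPKM of AC104053.1 against 1.51 to 1.57, and 0.880 FPKM of the lncRNA MSTRG.2333.1 against 1.54 to 1.70. Control replicate 1 had 43.1 FPKM of Col15a1 against 54.6 to 55.9. Nitroglycerin replicate 3 had 4.21 FPKM of Per3 against 5.18 to 5.30 and 12.4 FPKM of Xbp1 against 11.0 to 11.2, so these stood on their group's side of the controls. That library also had 44.6 FPKM of Mt2A against 9.21 to 11.7. Nitroglycerin replicate 2 had 4.35 FPKM at the assembled Npas2 locus against 2.88 to 2.92. Nitroglycerin replicate 1 had 0.863 FPKM at the assembled Lsr locus, listed at 0 in the other 3. That library also had a fat-marker score of 3.51 log2 against 2.01 to 2.19. The score was 1.92 ± 0.274 in controls and 2.45 ± 0.712 with nitroglycerin (two-sided exact permutation p = 0.200, n = 4 per group), which does not show that the groups were alike in it.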

How the results depend on the processing

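The number of genes called depended on most choices, while no named gene or list that passed in the main test changed direction. The annotated-transcript settings and all alternatives to the rescaled counts were chosen after seeing the data. Against 175 genes as deposited, there were 7 with a pseudocount of 0.1, 26 with no filter, 384 with the stricter filter, 17 after median-of-ratios rescaling, 15 after quantile normalization, 1936 with array weights, 3 with the fat-marker covariate and 828 when only rows with an annotated transcript were tested. Leaving out 1 library gave 5 to 284. Against 45 by the size rule, these were 7, 17, 28, 9, 9, 124 and 3 for the same settings up to the covariate, 162 at an unadjusted p, and 5 to 72 with a library left out. Rescaling also turned the split from 167 higher and 8 lower to 4 and 13, and quantile normalization to 5 and 10. Against 1 lncRNA, robust eBayes and the fat-marker covariate called 0 by limma (204 and 211 at an unadjusted p under 0.05), unadjusted p with a log2 difference of at least 1 gave 155, and leaving out a library gave 0 to 2. Against 3 lists, there were 11 with no filter, 7 after rescaling, 6 after quantile normalization, 8 with the covariate, 0 with an estimated correlation (3 at an unadjusted p under 0.05), 13 by fry, which asks only whether a list moves one way (all 13 higher, and none of them among the 3), and 3 to 6 with a library left out. Robust eBayes does not enter camera and was not run for lists. Against 17 rescaled genes, there were 4 with the covariate, 9 with factors from genes of at least 5 FPKM, 23 with factors from genes above 1 FPKM, and 1 to 31 with a library left out, the lowest without control replicate 4 and the highest without nitroglycerin replicate 2. Against 7 rescaled lists, there were 0 with an estimated correlation (3 at an unadjusted p), 3 by fry (1 higher and 2 lower) and 4 to 9 with a library left out. Fewer libraries or another set of tested rows account for part of this by construction, and otherwise the cause was not tested. The difference in fat-marker score was 0.54 log2, and 0.18 to 0.68 with a library left out. Over 493 values of named genes that passed as deposited, 214 passed again and 279 did not, all in the same direction. Over 649 values of named genes that did not pass as deposited, 40 passed and 10 changed direction without passing. Pde5a and Agtr1a were among the genes that passed in some setting (lowest limma adjusted p = 0.0346 and 0.0371). Read depth per gene was not analysed, so what depth alone limits is unknown.

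Libraries with the same replicate number correlated at 0.133, -0.011, -0.012 and 0.121 in their deviations from the group means. Of the 4 numbers, 2 matched best with their own, and the main test did not read them as pairs. However, the second principal component of the rescaled values (17.6% of the variance) rose with the number in both groups. It was -27.5, -10.3, 0.468 and 25.5 in controls 1 to 4, and -13.7, -12.2, 3.90 and 33.9 in nitroglycerin libraries 1 to 4. A structure shared by the number is therefore not excluded. With the number as a replicate block, limma called 0 genes (4037 at an unadjusted p under 0.05), 0 by the size rule (179), 0 lncRNAs (180) and 3 lists, and after rescaling 0 genes (1611) and 9 lists.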

Other observations

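Every test of an explanation for the 3 patterns here, and the counts of other splits for all genes, for rescaled genes and for loci listed at 0, were chosen after the results were seen. Only the split counts for the size rule, the lncRNAs and the lists were set out beforehand.

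Adjusted over their list alone, genes of the circadian clock were called in opposite directions after rescaling, but not as deposited. Of 17 measured members, Per3, Nr1d2 and Dbp (1.63 ± 0.582 to 4.50 ± 0.949 FPKM, n = 4 per group) rose over all genes as deposited, and Per3 alone passed after rescaling. Adjusted over the list alone, 5 were higher and 0 lower by limma as deposited (6 and 1 at an unadjusted p under 0.05). After rescaling, 5 were higher (Per3, Nr1d2, Dbp, Bhlhe40 and Tef) and 3 lower (Arntl, an assembled Npas2 locus and Nr1d1). Arntl, the activator partner of Clock, stood at 3.75 ± 1.55 and 2.48 ± 0.184 FPKM. Over all alternatives its log2 difference stayed between -0.684 and -0.195, so the scalings differ in calls rather than in its direction. These members were named after their values were seen. The list as a whole was not called by camera (limma, Benjamini-Hochberg adjusted p = 0.878, and 0.979 after rescaling).

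A difference in the time of day at collection may give such a pattern, and so may the treatment. The labels give no collection time, so the 2 cannot be told apart. A score of 8 output genes minus 5 genes set against them separated the groups (two-sided exact permutation p = 0.0286, n = 4 per group). The 5 were Arntl, Clock, Npas2, Cry1 and Nfil3, not all of them activators. Nr1d1 was counted among the 8 output genes although it was lower after rescaling. Its genes and their sides were chosen with the values in view, so it only restates the pattern and supports neither explanation.

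For the higher values of most genes in nitroglycerin libraries, median log2 difference 0.30, transcripts overlapping genes on the same strand held 10.5 ± 6.50% of aligned bases in controls and 4.33 ± 0.463% with nitroglycerin (two-sided exact permutation p = 0.0857, n = 4 per group). Control replicates 1 and 4 held 16.0% and 16.3%, of which AABR07015055.1 took 10.6% and 10.8%. Control replicates 2 and 3 held 4.10% and 5.76%, against 3.92% to 4.95% in nitroglycerin libraries. Rescaling to the bases outside these overlapping transcripts left a median of 0.22, and the library medians still separated by group (two-sided exact permutation p = 0.0286, n = 4 per group). This argues against these transcripts as the whole cause. Rescaling to the FPKM outside the 100 most abundant rows left 0.062, but dividing by the sum of genes that are mostly higher brings their median near 0 whatever the cause, so this supports no explanation. Rows with rRNA in their symbol, with LOC257642, held 15.1 ± 4.61% of the summed FPKM in controls and 10.7 ± 1.31% with nitroglycerin (two-sided exact permutation p = 0.114, n = 4 per group). That sum leaves out other abundant rows. By group means, AABR07015055.1 held 7.94% of the summed FPKM in controls and 2.11% with nitroglycerin, and AABR07015042.1 held 4.95% and 2.06%. AABR07015078.2 held 3.12% and 1.28%, and AABR07015067.1 held 2.76% and 2.57%. Some abundant rows went the other way, such as a U2 row (MSTRG.21269) at 0.521% and 1.13%. A few abundant transcripts taking more of the control libraries, whether leftover ribosomal RNA or tissue RNA, stay open. A change in total RNA per cell was not measured, since FPKM is relative.

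For the lower rescaled values of the matrix and contractile lists, whose calls were lost with an estimated correlation, a trend with expression level was examined. The rescaled median of the matrix list was at percentile 0 of 10000 random lists matched on mean expression. Random members were drawn independently, so correlated lists can reach such extremes, and this percentile does not decide. The uncalled immediate early and general adipocyte lists were both at percentile 100. In the highest decile of expression the rescaled median of all genes was -0.077, against -0.37 for the matrix list. A smaller share of fibroblasts was neither shown nor excluded: the fibroblast score was 4.89 ± 0.37 log2 in controls and 4.92 ± 0.20 with nitroglycerin (two-sided exact permutation p = 0.886), 4 of 13 fibroblast markers were higher and 0 lower adjusted over the list alone as deposited (after rescaling 1, Gsn), and the matrix score minus the fibroblast score differed by -0.36 log2 (p = 0.143, n = 4 per group). A smaller share of smooth muscle cells also stays open, since the changes of 4 other cell-type lists were no more spread than in other splits (58 of 70 splits as spread). The treatment itself is untested against these, so the explanations cannot be told apart.

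Across the 35 splits of the 8 libraries, only the real one gave as many as 175 genes (highest other 6), 45 by the size rule (highest other 6) or 17 after rescaling (highest other 10). These 3 counts come from overlapping tests on the same libraries and stand at 1 split of 35, the lowest share possible. They argue against chance alone only at that limit. Library factors separated the real groups and were mixed in other splits, which the deposited counts can reflect. Chance was not excluded for the 1 lncRNA (10 of 35 splits, highest other 1), the 3 lists (26 of 35, highest other 13) or the 7 rescaled lists (12 of 35, highest other 13). A structure of the samples, or a preset correlation below most of the estimated ones (not that of the skeletal muscle list, -0.099), may lie behind splits that call 13 lists, and neither was tested. Chance was also not excluded for the 5 genes listed at 0 in 1 whole group and at least 1 FPKM throughout the other (11 of 35 splits, highest other 9), or for 7 such lncRNAs at 0.5 FPKM (15 of 35, highest other 11).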
